A study of Drosophila melanogaster with 8 samples.

How the data were processed

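Total RNA of L57 cells, a cultured Drosophila melanogaster line, was labelled with biotin and measured on 8 Affymetrix Drosophila arrays. The labels form 4 groups of 2 arrays: DMSO, the solvent control, and 1 µM juvenile hormone III (JH III) for 3, 6 or 12 h. JH III is the insect sesquiterpenoid hormone that maintains larval characters and regulates reproduction. The source label of 1 DMSO array mentions embryos, while every growth protocol describes cultured L57 cells. The series text lists DMSO as 0 h, so no DMSO array was matched in time to the 3, 6 or 12 h of exposure. The labels do not say that replicates came from separate cultures, so every p-value measures the spread between these arrays, which is perhaps technical alone.

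The deposited values are MAS5 signal intensity per probe set on a linear scale (MAS5 version not given), scaled by the authors to a common trimmed mean. The mean after trimming 2% at each end was 500.1 on the 7 intact arrays. The table held 14010 probe sets: 44 array controls, 9 of them hybridization controls, and 13966 others. JH III 6 h replicate 2 held 2 unreadable stretches, 3151 probe sets or 22.5% of the table, all zeros except for 5 impossible values. These were treated as missing, which left 1 array at 6 h for 2611 of the probe sets tested. For these the error at 6 h takes its spread from the other groups, and the lone array is assumed to vary like them. Outside these stretches the trimmed mean of this array was 376.2, inside the 373.6 to 379.9 of the 7 others. Background correction could not be redone from signal values.

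Values were analysed as log2(signal + 25.0), the added constant being 5% of the mean trimmed signal. Controls were left out, as were 5586 dim probe sets with a mean log2 value under the 40th percentile, a signal of 61.5. The 8380 that stayed included 7450 with 1 gene symbol, which covered 6865 genes, and 261 with probes shared between genes. Symbols came from the annotation of the array's probe sets and were looked up in a RefSeq gene table, but probes of this early array were not realigned, so some may not match current gene models. All 8 arrays entered 1 fit of 4 group means in limma 3.58.1 (R 4.3.3) with a variance trend, and errors are standard errors from this fit unless marked SD. P-values are two-sided and were adjusted by Benjamini-Hochberg over the 8380 probe sets, with 0.05 as the threshold. Comparisons were each JH III time against DMSO, their mean against DMSO, any difference among the 4 groups, and the 3 differences between times. Replicate numbers did not pair the arrays (correlations of deviations from -0.047 to 0.066), so no pairing was used, and neither an outlier test nor a count of other groupings was made with groups of 2. The number of arrays limits the precision.

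Fixed lists of genes covered JH reception and JH-responsive genes, JH synthesis and turnover, ecdysone-responsive genes, nuclear receptors, cytochrome P450, glutathione and UDP transferases, heat shock proteins, endoplasmic reticulum stress, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, ribosome biogenesis, translation factors, proteasome, oxidative phosphorylation, DNA replication and S phase, mitosis, immune response, glycolysis, lipid and sterol metabolism, amino acid transporters, insulin and TOR pathway, immediate early and stress kinase genes, apoptosis, autophagy and lysosome, and actin and adhesion. Further lists held markers of hemocytes, neurons, muscle, fat body and germline. Of 27 hemocyte markers 19 passed the filter with a probe set, against 4 of 19 neuronal and 6 of 21 muscle markers. The 30 lists, the rule for naming genes, the filter, the model and most of the other settings tried were set before the data were examined. Each gene entered with its brightest probe set, and 29 lists had the 5 members needed for a test (4 neuronal markers did not). Lists were tested against the other genes of the 6865, each with its brightest probe set, with limma's camera at a preset correlation of 0.01, adjusted over lists and times. They were tested again with an estimated correlation, and with fry, which asks whether a list moves on balance one way, both on probe sets readable on all 8 arrays.

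Genes named are, for each time against DMSO, the 12 largest rises and 12 largest falls with 1 symbol, past the threshold and with the JH III arrays beyond both DMSO arrays. For the mean and for differences between times they are the 6 of each, or the 8 with the smallest p where none of those ranked passed. Probe sets unreadable on JH III 6 h replicate 2 were left out of every ranking in which 6 h entered. All members of the JH list, EcR, and the 4 members of any other list with the largest mean change were added. Chosen after the data were seen were 4 alternatives: use of probe sets readable on all 8 arrays alone, zeros kept as values, counts by gene, and fold thresholds of 1.5 and 2. The settings fixed beforehand were quantile normalization, median centring, no added constant (floor at the 1st percentile, 2.49) or 20% of the trimmed mean (100.02), no filter or the 60th percentile, no variance trend, a replicate block, only the 2 groups compared, the mean of a gene's probe sets, and each array left out. A search of promoters for DR4, a direct repeat element, was not run, because the reference in hand held no genome sequence.

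The fit was tested on simulated data with 200 changed probe sets of 8380, in 10 simulations. At 3 h it found 43.4% of changes of 1.5-fold, 73.7% of 2-fold and 95.5% of 4-fold, and at 6 h 36.7%, 71.6% and 93.5%. False calls made up 6.34% and 5.47% of those called. A list of 60 genes shifted by 1.2-fold was called in 10 of 10 simulations, and an unshifted list in 0 of 10 by limma's camera. Simulated probe sets varied independently and these list p-values were unadjusted. The simulations therefore cannot show how often camera calls lists whose members vary together.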

Results

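Transcript levels were measured in L57 cells under DMSO and after 3, 6 and 12 h of JH III, with 2 arrays per group. Over the 10859 probe sets readable on all 8 arrays, median signal was 70.9 and 72.9 on the DMSO arrays. It was 85.0 and 81.8 at 3 h, 81.2 and 85.9 at 6 h, and 82.1 and 79.4 at 12 h. Replicates correlated across these probe sets at 0.972 to 0.980, and arrays of different groups at 0.966 to 0.977. The median change of the 8380 probe sets tested was 0.03, 0.05 and 0.00 on the log2 scale at 3, 6 and 12 h. Centring each array on its median moved these to -0.13, -0.10 and -0.12, so every change below is relative to the authors' scale. List medians moved down with it, at 3 h from -0.25 to -0.41 for oxidative phosphorylation and from 0.43 to 0.27 for hemocyte markers. Each gene named as changed against DMSO had all of its readable JH III arrays beyond both DMSO arrays.

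The 3 h arrays were compared with DMSO to find early changes under JH III. The long non-coding RNA gene lncRNA:CR42862 rose 4.67-fold (log2 change 2.22 ± 0.12, adjusted p = 6.66e-05) on the scale of log2(signal + 25.0), which holds for every fold given, and its other probe set rose by 1.57. Its signal went from 229 ± 0.264 (SD, n = 2) to 1165 ± 168 (SD, n = 2). Pkc98E, a protein kinase C, rose 4.51-fold (2.17 ± 0.31, adjusted p = 0.00187), and its other probe set gave 0.91. Atg10, an enzyme of autophagosome formation, rose 4.01-fold (2.01 ± 0.30, adjusted p = 0.00254), and bun, a TSC22-family transcriptional regulator, rose 3.34-fold (1.74 ± 0.12). The testis transcription factor gene topi rose by 1.99 ± 0.36. For ps, which encodes an RNA-binding splicing regulator, 1 probe set rose by 1.89 ± 0.31 and another gave 0.48 (adjusted p = 0.101). PCB, pyruvate carboxylase, fell by 2.09 ± 0.19 on the log2 scale (adjusted p = 0.000368), and ND-B12, a subunit of respiratory complex I, fell by 1.15 ± 0.10 (adjusted p = 0.000288). The Notch-responsive repressor gene E(spl)mbeta-HLH fell by 1.17 ± 0.13 and CG5254 fell by 1.21 ± 0.09. For CG32687 1 probe set fell by 1.81 ± 0.29 and the other gave -1.10 (adjusted p = 0.136). The other 6 of the 12 largest rises and 6 of the 12 largest falls passed with all 8 arrays and not without 1 of the DMSO, 3 h or 6 h arrays. By limma 1572 probe sets changed, 888 higher and 684 lower (717 and 613 genes), and 196 changed at least 2-fold. With median centring the split was 507 higher and 1413 lower. The count was 752 and 581 without DMSO replicates 1 and 2, 693 and 798 without 3 h replicates 1 and 2, 875 without the variance trend, and 942 on probe sets readable on all arrays.

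**Figure D1:**
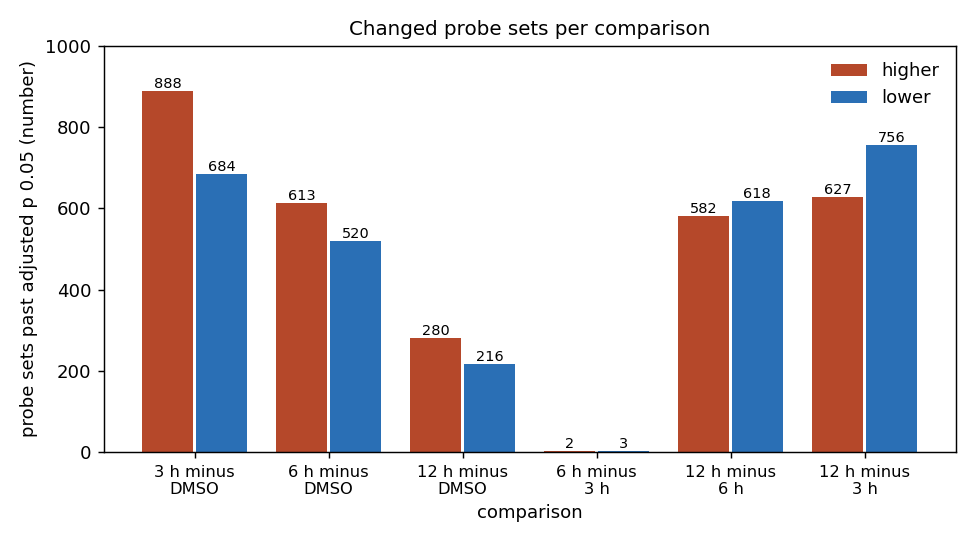
Number of probe sets past an adjusted p of 0.05 (vertical axis) in each comparison, with bars for higher and lower. The bars show 888 higher and 684 lower at 3 h, 280 and 216 at 12 h, and 5 in all between 6 h and 3 h; with median centring the split at 3 h was 507 and 1413.

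The mitochondrial ribosomal protein and oxidative phosphorylation lists lay below DMSO at 3 h by camera at its preset correlation. On the 3 h arrays the ratio of 3' to 5' signal, a sign of RNA integrity, lay 0.19 ± 0.13 above DMSO for the actin control. The same ratio lay 0.29 ± 0.13 above DMSO for eIF4A and gave -0.025 ± 0.04 for Gapdh. Of 65 mitochondrial ribosomal proteins 38 fell and 1 rose (43 and 1 adjusted over the list alone), with a median of -0.34 (camera adjusted p = 3.74e-15; adjusted p = 0.228 with an estimated correlation). Within it mRpS34 fell by 0.61 ± 0.10 and mRpS16 fell by 0.54 ± 0.08. Of 64 oxidative phosphorylation genes 31 fell and 1 rose (37 and 3 adjusted over the list alone), with a median of -0.25 (camera adjusted p = 9.67e-11; adjusted p = 0.342 with an estimated correlation). The complex I subunit genes ND-B18 and ND-19 fell by 0.66 ± 0.08 and fell by 0.65 ± 0.07. Ribosome biogenesis genes fell in 11 of 46 members, and rose in 1 (14 and 1 adjusted over the list alone; median -0.24, camera adjusted p = 0.000184; adjusted p = 0.228 with an estimated correlation), and 1 probe set of Ns3, a nucleostemin-family GTPase gene, fell by 0.67 ± 0.08, while the other gave -0.30 (adjusted p = 0.748).

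Insulin and TOR pathway genes rose in 10 of 18 members at 3 h and fell in 0 by limma (10 and 0 adjusted over the list alone), with a median of 0.56. ImpL2, a secreted protein that binds insulin-like peptides and restrains the pathway, rose by 0.79 ± 0.09 (adjusted p = 0.00107). Another restraint, the TOR inhibitor gene scyl, rose by 1.26 ± 0.22 (adjusted p = 0.00623; 0.0502 without DMSO replicate 2). The insulin receptor gene InR rose by 1.18 ± 0.25 (adjusted p = 0.0112; up to 0.0736 without DMSO replicate 1 or either 3 h array), and Mnt, a Myc antagonist, by 1.14 ± 0.26 (adjusted p = 0.019; up to 0.103 without DMSO replicate 2 or either 3 h array). Hemocyte markers rose in 11 of 19 and fell in 1 (12 and 1 adjusted over the list alone), with a median of 0.43. Among them Hml, the blood cell gene hemolectin, rose 1.82-fold (0.87 ± 0.06). For the matrix gene Ppn 1 probe set rose by 0.92 ± 0.09 and the other gave 0.49 (adjusted p = 0.414). Immediate early and stress kinase genes rose in 4 of 14 (5 adjusted over the list alone; median 0.23), with sty, the receptor kinase inhibitor sprouty, up 2.48-fold (1.31 ± 0.08) and the ETS repressor gene aop up by 0.90 ± 0.11. The camera adjusted p was 0.000184, 0.000184 and 0.0206 for these 3 lists, and the adjusted p was 0.289, 0.289 and 0.342 with an estimated correlation. The immediate early call was lost on probe sets readable on all arrays (adjusted p = 0.082).

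Autophagy and lysosome genes rose in 8 of 27 and fell in 1 at 3 h (8 and 1 adjusted over the list alone), with a median of 0.10 that became -0.06 with median centring (camera adjusted p = 0.025 and 0.0746; adjusted p = 0.228 with an estimated correlation). The vesicle tethering gene lt rose 2.56-fold (1.35 ± 0.13), the proton pump subunit gene Vha26 by 0.72 ± 0.07 and the lysosomal membrane gene Lamp1 by 0.71 ± 0.10. Actin and adhesion genes rose in 6 of 19 (6 adjusted over the list alone; median 0.28, camera adjusted p = 0.00335; adjusted p = 0.342 with an estimated correlation), a call lost on probe sets readable on all arrays (adjusted p = 0.082). Translation factors fell in 13 of 37 and rose in 4 (14 and 5 adjusted over the list alone; median -0.15). The poly(A)-binding protein gene pAbp rose 2.58-fold with 1 probe set (1.37 ± 0.08) and by 0.78 with the other, the scaffold gene eIF4G1 rose by 0.80 ± 0.08, and eIF3g1 fell by 0.50 ± 0.07. Heat shock proteins fell in 3 of 13 (3 adjusted over the list alone; median -0.07): Hsp68 fell by 1.14 ± 0.09, Hsp26 fell by 0.90 ± 0.07 and Hsp27 fell by 0.75 ± 0.09. Ecdysone-responsive genes rose in 6 of 13 and fell in 1 (6 and 1 adjusted over the list alone; median 0.54), and cytosolic ribosomal proteins fell in 1 of 29 (0 adjusted over the list alone by limma; median -0.08). For these 4 lists the camera adjusted p was 0.0288, 0.0288, 0.0183 and 0.0206, and the adjusted p was 0.367, 0.342, 0.421 and 0.708 with an estimated correlation. Without DMSO replicate 2 the 4 calls were lost (adjusted p = 0.0696, 0.0652, 0.0652 and 0.14), as were those of translation factors (0.108) and cytosolic ribosomal proteins (0.251) without 3 h replicate 1, and quantile normalization gave 0.233, 0.216 and 0.847 for all but the ecdysone list.

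The 6 h arrays extended the comparison with DMSO to a longer exposure. The same non-coding RNA, lncRNA:CR42862, rose 4.06-fold (2.02 ± 0.12, adjusted p = 7.67e-05), 1 probe set of Pkc98E rose by 1.91 ± 0.31 (the other gave 0.50, adjusted p = 0.178), bun by 1.67 ± 0.12, fok by 1.52 ± 0.12 and mthl4, a methuselah-like receptor gene, by 1.78 ± 0.33. PCB fell by 2.27 ± 0.19 (adjusted p = 0.000404), CG5254 fell by 1.54 ± 0.09 (adjusted p = 7.4e-05), and ND-B12 and the chaperone gene Hsp68 fell by 1.15 ± 0.10 and fell by 1.16 ± 0.09. The rankings at 6 h held only probe sets readable on both 6 h arrays. The other 6 of the 12 largest rises and 8 of the 12 largest falls passed with all 8 arrays and not without 1 of them. By limma 1133 probe sets changed, 613 higher and 520 lower (491 and 467 genes), 337 of them with 1 readable array at 6 h. With median centring the split was 349 higher and 1141 lower. Without 6 h replicate 1, the 2611 probe sets unreadable on 6 h replicate 2 had no 6 h value and were not tested. The count was 470 and 354 without DMSO replicates 1 and 2, 370 without 6 h replicate 1, and 472 without the variance trend.

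On the 6 h arrays the ratio of 3' to 5' signal lay 0.19 ± 0.10 above DMSO for actin, 0.060 ± 0.03 for Gapdh and 0.067 ± 0.14 for eIF4A. Mitochondrial ribosomal proteins fell in 38 of 65 members at 6 h and rose in 0 by limma (median -0.42). Adjusted over the list alone, 49 of them fell and 1 rose. Within them mRpL54 fell by 0.91 ± 0.14 (1 readable array) and mRpS34 fell by 0.63 ± 0.10. Oxidative phosphorylation genes fell in 28 of 64 (36 adjusted over the list alone; median -0.25), and ND-B18 and ND-PDSW each fell by 0.72, with errors of 0.08 and, from 1 readable array, 0.09. Ribosome biogenesis genes fell in 10 of 46 (11 adjusted over the list alone; median -0.24), and the same probe set of Ns3 fell by 0.59 ± 0.08. The camera adjusted p was 8.55e-21, 3.74e-15 and 4.16e-06 for these 3 lists, and the adjusted p was 0.228, 0.313 and 0.228 with an estimated correlation.

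Hemocyte markers rose in 7 of 19 at 6 h (9 rose and 1 fell adjusted over the list alone; median 0.36), Hml by 0.88 ± 0.06. Insulin and TOR pathway genes rose in 4 of 18 (6 adjusted over the list alone; median 0.58), and ImpL2 rose 2.47-fold (1.30 ± 0.11, 1 readable array). Autophagy and lysosome genes rose in 7 of 27 (8 rose and 1 fell adjusted over the list alone; median 0.21), with Atg13, part of the complex that starts autophagy, at 0.91 ± 0.08 and lt at 1.01 ± 0.13. The camera adjusted p was 0.000154, 0.000183 and 0.00418 for these 3 lists, and the adjusted p was 0.289, 0.289 and 0.228 with an estimated correlation. Lipid and sterol metabolism genes rose in 5 of 23 and fell in 1 (6 and 1 adjusted over the list alone; median 0.21). The fatty acid synthase gene FASN1 rose 1.96-fold (0.97 ± 0.07), Acsl by 0.88 ± 0.12 (1 readable array) and the lipid regulator SREBP by 0.69 ± 0.10. Actin and adhesion genes rose in 2 of 19 (1 adjusted over the list alone; median 0.28), ecdysone-responsive genes rose in 2 of 13 and fell in 1 (4 and 1 adjusted over the list alone; median 0.61), and cytosolic ribosomal proteins fell in 3 of 29 (3 adjusted over the list alone; median -0.11, which became 0.00 with quantile normalization, adjusted p = 0.698). For these 4 lists the camera adjusted p was 0.0232, 0.00543, 0.025 and 0.00304, and the adjusted p was 0.313, 0.342, 0.342 and 0.682 with an estimated correlation. On probe sets readable on all arrays the lipid, actin and ecdysone calls were lost (camera adjusted p = 0.0518, 0.0961 and 0.173). Leaving out 6 h replicate 1 likewise removed the members unreadable on 6 h replicate 2, so those lists were smaller too. The lipid call was lost without DMSO replicate 1 (adjusted p = 0.0643) and with median centring (0.0618). Without 6 h replicate 1 the other 3 were lost (0.113, 0.0563 and 0.367), and without DMSO replicate 2 the ecdysone call (0.0829). Heat shock proteins were not called (camera adjusted p = 0.157), with a median of 0.03 that changed sign under both other scalings and a mean of -0.21, and Hsp26 fell by 1.65 ± 0.08 (1 readable array).

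**Figure D2:**
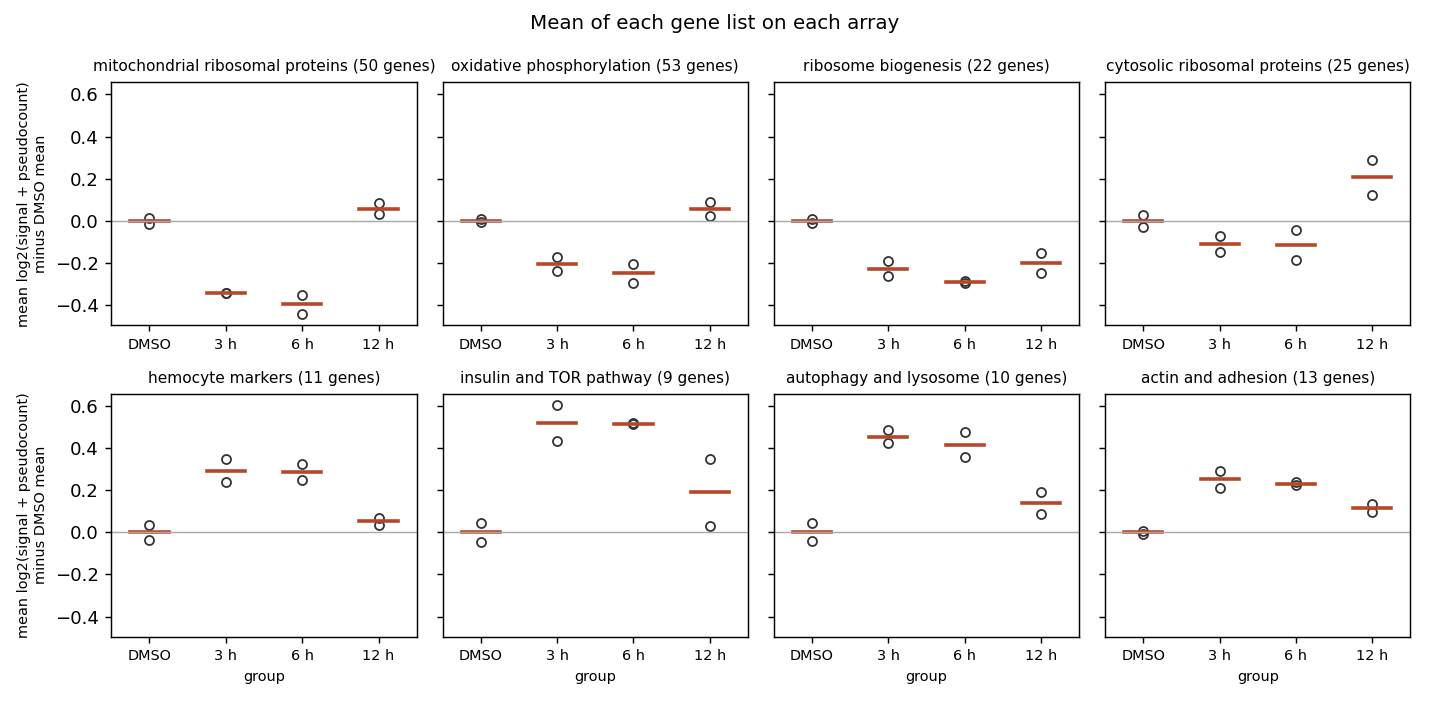
Mean log2 value of 8 gene lists on each array, minus the mean of the DMSO arrays (vertical axis, log2), for members readable on all 8 arrays. For autophagy and lysosome these are 10 of 27 members, with means of 0.42 and 0.48 on the 3 h arrays, where the median of the full list was 0.10. Mitochondrial ribosomal proteins and oxidative phosphorylation lie below DMSO on the 3 h and 6 h arrays and hemocyte markers above; cytosolic ribosomal proteins lie above at 12 h on this scale, where their median was 0.22, and quantile normalization gave 0.01.

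The 12 h arrays gave the longest exposure, again against the DMSO arrays listed as 0 h. AgmNAT, an arylalkylamine N-acetyltransferase family gene, rose 4.33-fold (2.11 ± 0.27, adjusted p = 0.00382), and ND-B14.5A, a complex I subunit gene, rose 2.39-fold (1.26 ± 0.07, adjusted p = 0.000191). CG11523 fell by 1.44 ± 0.12 (adjusted p = 0.00116) and Arc1, a Gag-like gene, fell by 0.90 ± 0.09 (adjusted p = 0.00118). Values that had changed at earlier times and did not pass at 12 h included 0.05 for Hml (adjusted p = 0.724), 0.10 for ImpL2 and 0.12 for FASN1. The added hybridization controls, which carry no RNA of the cells, lay 0.54 ± 0.16 above DMSO on the 12 h arrays, and the Gapdh control gave -0.61 ± 0.01. The other 10 of the 12 largest rises and 10 of the 12 largest falls passed with all 8 arrays and not without 1 of them. By limma 496 probe sets changed, 280 higher and 216 lower (228 and 196 genes), 36 of them at least 2-fold. With median centring the count was 889, split as 181 higher and 708 lower. The count was 82 and 84 without DMSO replicates 1 and 2, 303 without either 3 h array, 301 without 12 h replicate 2, 305 with a replicate block, 301 from the DMSO and 12 h arrays alone, 284 on probe sets readable on all arrays and 37 without the variance trend.

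On the 12 h arrays the ratio of 3' to 5' signal lay 0.21 ± 0.12 above DMSO for actin, 0.012 ± 0.07 for Gapdh and 0.17 ± 0.15 for eIF4A. Cytosolic ribosomal proteins rose in 6 of 29 members at 12 h (14 adjusted over the list alone). Their median was 0.22 (camera adjusted p = 1.75e-08, and 0.469 with an estimated correlation). Quantile normalization brought this median to 0.01 (camera adjusted p = 0.68). Ribosome biogenesis genes fell in 7 of 46 and rose in 2 (15 and 4 adjusted over the list alone; median -0.20), and 1 probe set of Ns3 fell by 0.78 ± 0.08 (adjusted p = 0.00129), the other giving -0.40. Endoplasmic reticulum stress genes fell in 3 of 16 (6 adjusted over the list alone; median -0.13). The camera adjusted p was 7.41e-05 and 0.00516 for these lists, and the adjusted p was 0.228 and 0.313 with an estimated correlation. Translation factors fell in 8 of 37 and rose in 3 (11 and 6 adjusted over the list alone; median -0.16), 1 probe set of pAbp by 0.93 ± 0.08 and the other by 0.74. DNA replication and S phase genes fell in 3 of 33 and rose in 1 (4 and 1 adjusted over the list alone; median -0.14), and ecdysone-responsive genes rose in 2 of 13 (2 adjusted over the list alone; median 0.21). For these 3 lists the camera adjusted p was 0.0288, 0.0271 and 0.0334, and the adjusted p was 0.342, 0.304 and 0.342 with an estimated correlation. All 3 calls were lost without DMSO replicate 2 (adjusted p = 0.0696, 0.0547 and 0.12) or 12 h replicate 2 (0.108, 0.0546 and 0.0806), and those of DNA replication and ecdysone without 12 h replicate 1 (0.0648 and 0.0602). The DNA replication call was also lost with quantile normalization (camera adjusted p = 0.0685) and with the filter at the 60th percentile (0.0768). Mitochondrial ribosomal proteins (median 0.03, and -0.10 with median centring) and oxidative phosphorylation (median -0.01, and -0.14 with median centring) were not called, with camera adjusted p of 0.483 and 0.972.

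The list of JH reception and JH-responsive genes asked whether known targets of the hormone moved. JhI-26, a gene named for its induction by JH, rose 1.57-fold at 3 h (0.65 ± 0.10, adjusted p = 0.00338) and 1.90-fold at 6 h (0.92 ± 0.12, 1 readable array), and gave 0.26 ± 0.10 at 12 h (adjusted p = 0.161). Pepck1, an enzyme of gluconeogenesis, fell by 0.58 ± 0.08 at 3 h (adjusted p = 0.00156) and fell by 0.45 ± 0.08 at 6 h (adjusted p = 0.00683; 0.0662 without DMSO replicate 2), and gave -0.22 at 12 h. Kr-h1, the transcription factor through which JH represses metamorphosis, gave -0.62 ± 0.27 at 3 h (adjusted p = 0.147), 0.34 at 6 h (1 readable array, adjusted p = 0.551) and -0.52 at 12 h (adjusted p = 0.301). The JH receptor genes did not pass either: Met gave 0.02, 0.88 and 0.77, and gce gave 0.58, -0.31 and 0.16 with 1 probe set and 0.53, 0.64 and 0.54 with another (lowest adjusted p = 0.0559 and 0.0682). The ecdysone-induced transcription factor gene br had 1 of its probe sets up by 1.14 ± 0.25 at 3 h (adjusted p = 0.0178), a call lost without any of the DMSO or 3 h arrays (up to 0.114), while the others gave 0.25 and 0.23. Nup358 at 3 h (0.60 ± 0.14, adjusted p = 0.0199) lost its call without DMSO replicate 1, DMSO replicate 2 or 3 h replicate 1 (up to 0.126). JhI-21 at 6 h (0.72 ± 0.19, 1 readable array, adjusted p = 0.0397) lost its call without either DMSO array. It also lost it without 6 h replicate 2, which held no value for this gene and acted only through the shared spread and the adjustment. The call rests on 6 h replicate 1, without which JhI-21 has no 6 h value. Of the 15 members 3 rose and 1 fell at 3 h, 2 and 1 at 6 h, and 0 and 0 at 12 h by limma (4 and 1, 2 and 1, and 0 and 0 adjusted over the list alone). The list medians of 0.02, 0.11 and 0.16 were not called (camera adjusted p = 0.584, 0.726 and 0.72), and those of 3 and 6 h turned negative with median centring. EcR, the ecdysone receptor gene, fell below the filter. Without it neither probe set passed in limma at any time (adjusted p = 0.594 to 0.853). The signals were 52.5 ± 36.0, 79.1 ± 70.1, 36.7 ± 4.75 and 33.5 ± 3.73 (SD, n = 2) in DMSO and at 3, 6 and 12 h for 1 probe set, and for the other 8.74 ± 2.56 in DMSO and 38.3 ± 47.1 at 12 h.

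**Figure D3:**
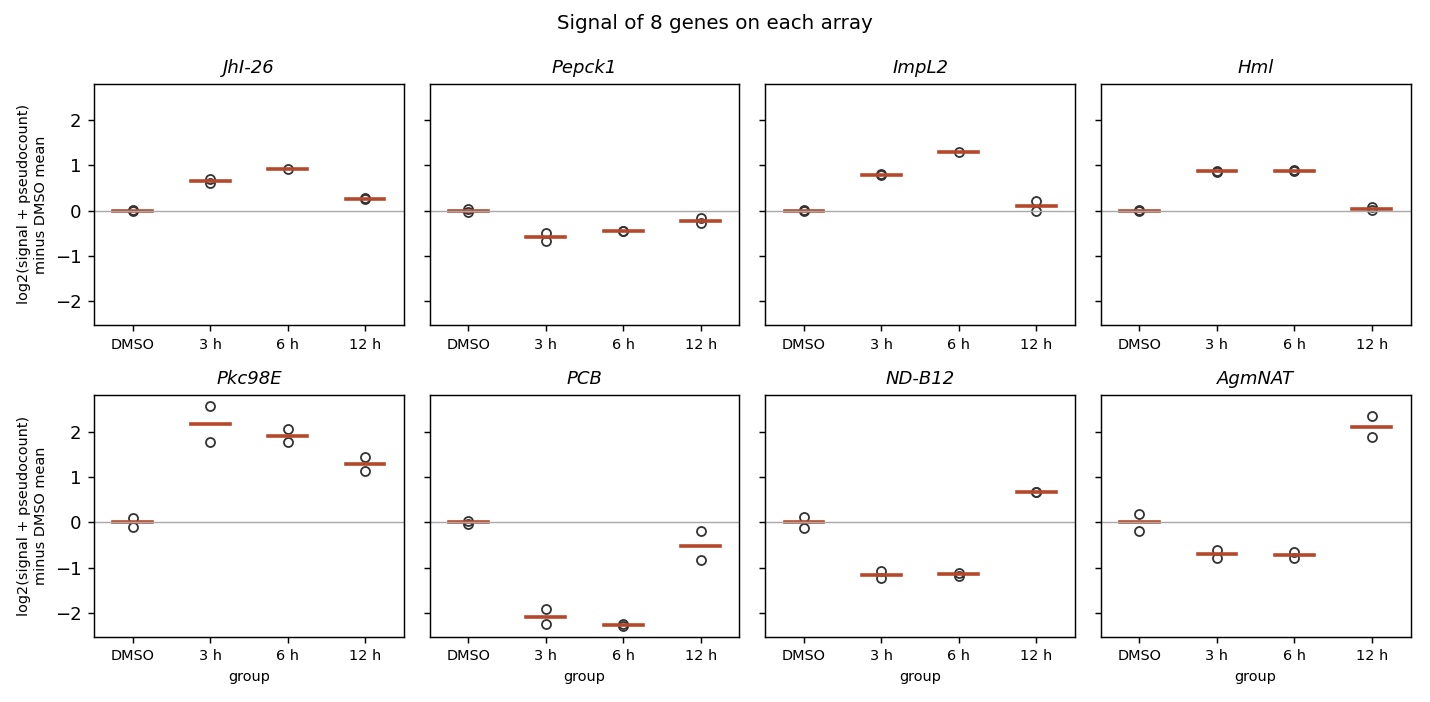
Log2 value of 8 genes on each array minus the mean of the DMSO arrays (vertical axis, log2), by group, with open circles for arrays and a bar for the group mean. Hml and JhI-26 lie above DMSO at 3 and 6 h, PCB and ND-B12 below, and AgmNAT lies above at 12 h; JhI-26 and ImpL2 have 1 readable array at 6 h.

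The mean of the 3 times against DMSO pooled the exposures. On average lncRNA:CR42862 rose by 1.77 ± 0.10 (adjusted p = 8.72e-05) and 1 probe set of Pkc98E by 1.79 ± 0.25 (adjusted p = 0.00284), the other giving 0.61 (adjusted p = 0.0534), while PCB fell by 1.62 ± 0.16, CG5254 fell by 1.04 ± 0.07 and Hsp68 fell by 0.83 ± 0.07. By limma 1213 probe sets changed, 667 higher and 546 lower (537 and 501 genes), and with median centring 363 were higher and 1381 lower. The count was 334 and 165 without DMSO replicates 1 and 2, 790 without 3 h replicate 1, 581 without 6 h replicate 1, 425 without the variance trend and 741 on probe sets readable on all arrays. At any of the 3 times 965 genes were higher and 836 lower, 68 of them both, and 66 were higher and 50 lower at all 3. By a mean fold of at least 1.5 at any time, without a test, 1195 genes were higher and 641 lower, and by at least 2, 282 were higher and 98 lower. The series description counts 497 genes raised and 228 reduced by JH without the rule for the call. Any difference among the 4 groups was found at 1972 probe sets, which was 1179 and 1077 without DMSO replicates 1 and 2, 1231 and 1268 without 3 h replicates 1 and 2, 1048 without 6 h replicate 1, 811 without the variance trend and 1242 on probe sets readable on all arrays.

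Between 6 h and 3 h the tests asked whether the response moved on. E(spl)mbeta-HLH rose from 3 h to 6 h by 1.77 ± 0.13 (adjusted p = 0.00161), and GstE1, a glutathione transferase, rose by 0.56 ± 0.07 (adjusted p = 0.0306), a call lost without any single array of DMSO, 3 h or 6 h (up to 0.208). The other 3 probe sets, named after their values were seen, were Hsp26, which fell by 0.75, Oda, an inhibitor of polyamine synthesis, which fell by 0.97, and aqz, which fell by 0.98, all 3 with 1 readable array at 6 h. By limma these 5 of 8380 differed, against 1005 at an unadjusted p under the same threshold. The count was 1 without either DMSO array or either 3 h array, 2 without 6 h replicate 1, and 15 with quantile normalization.

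From 6 h to 12 h AgmNAT rose by 2.84 ± 0.27 (adjusted p = 0.000259), PCB by 1.75 ± 0.19 (adjusted p = 0.000597) and CG3603 by 1.73 ± 0.20. The complex I genes ND-B12, ND-B14.5A and ND-B14.5B rose by 1.82 ± 0.10, 1.65 ± 0.07 and 1.57 ± 0.09 (adjusted p = 1.58e-05, 1.58e-05 and 2.08e-05). The ether lipid enzyme gene Gnpat fell by 1.75 ± 0.32 (adjusted p = 0.00714). From 3 h to 12 h AgmNAT rose by 2.81 ± 0.27, ND-B12 by 1.82 ± 0.10, ND-B14.5B by 1.73 ± 0.09 and CG17806 by 2.01 ± 0.31. JhI-26, with 1 readable array at 6 h, fell by 0.66 ± 0.12 from 6 h to 12 h (adjusted p = 0.00914). Between 12 h and 6 h 1200 probe sets differed, 582 higher and 618 lower at 12 h, and between 12 h and 3 h 1383, 627 higher and 756 lower. With median centring the first was split as 620 higher and 449 lower, and the second as 693 higher and 578 lower. The first count was 458 without 6 h replicate 1, 670 from the 2 groups alone and 517 without the variance trend, and the second 561 and 667 without 3 h replicates 1 and 2, 685 without the variance trend and 864 on probe sets readable on all arrays.

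The mitochondrial ribosomal protein and oxidative phosphorylation lists lay higher at 12 h than at 6 h by camera at its preset correlation. Mitochondrial ribosomal proteins rose in 29 of 65 members from 6 h to 12 h and fell in 0 by limma (42 and 0 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 1.26e-20; adjusted p = 0.451 with an estimated correlation). Oxidative phosphorylation genes rose in 27 of 64 (29 adjusted over the list alone), with a median of 0.20 (camera adjusted p = 1.11e-12; adjusted p = 0.461 with an estimated correlation). From 3 h to 12 h hemocyte markers fell in 13 of 19 and rose in 1 (13 and 2 adjusted over the list alone), with a median of -0.47 (camera adjusted p = 0.000174; adjusted p = 0.451 with an estimated correlation). Over the 3 times against DMSO 28 of 87 list tests were called by camera, 41 by fry and 22 by both, and 0 with an estimated correlation in limma's camera, where 12 had an unadjusted p under the threshold. Between times 18 of 87 were called by camera and 34 by fry.

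The responses at the 3 times were compared across probe sets, which are not independent replicates and share the DMSO arrays. Log2 changes at 3 and 6 h correlated at 0.740, against 0.478 in 100 simulations without an effect, and those at 3 and 12 h at 0.414 against 0.501, and at 6 and 12 h at 0.377 against 0.479. The covariances of these 3 pairs were 0.127, 0.0600 and 0.0521, each above the 0.0271 of the simulations. Noise was drawn independently for each simulated array, so a deviation common to both DMSO arrays, which would raise all 3 covariances, was not included. Probe sets higher at both 3 and 6 h numbered 471 and lower at both 381. Opposite calls at 3 and 6 h numbered 1. Those higher at both 3 and 12 h numbered 109 and lower at both 97, while 66 were lower at 3 h and higher at 12 h and 2 went the other way. For 6 and 12 h the numbers were 87 higher and 63 lower at both, 64 lower and then higher, and 4 the other way. Calls made independently at the same rates would share 65.0 higher and 42.4 lower at 3 and 6 h. For 3 and 12 h they would share 29.7 and 17.6, and for 6 and 12 h 20.5 and 13.4. The shared DMSO arrays are not allowed for in these values. The simulations held no effect, so their shared calls, at most 0.02 on average for any pair and direction, set no measure for these overlaps.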

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

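The tests of scaling, of shared DMSO arrays and of hybridization controls were chosen only after the results they measure were seen, and the 2 brightness-matched tests before.

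The fall of mitochondrial ribosomal protein and oxidative phosphorylation genes at 3 and 6 h, and their rise from there to 12 h, was weighed first. Scaling between arrays was argued against by quantile normalization, under which the 4 list medians stayed at -0.20 or lower, though the size depended on scaling, with median centring giving -0.50 and -0.58 for mitochondrial ribosomal proteins and -0.41 and -0.40 for oxidative phosphorylation at 3 and 6 h. A shift of all probe sets of like brightness was argued against by 10000 matched lists per comparison, whose lowest median was -0.25 at 3 h for mitochondrial ribosomal proteins (-0.34 in the list) and no lower elsewhere, and 0 lists lay as low in any of the 4 comparisons. An effect of JH III and an effect of time in culture remain open and untested, because no DMSO array matched 3, 6 or 12 h. A batch shared by the 3 and 6 h arrays also remains open, since the labels give no batch. RNA integrity, read from the ratios of 3' to 5' signal given above, was not tested as a cause. A JH III effect may account for the fall, a hypothesis formed on these arrays that DMSO arrays at the same times would test.

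Responses at 3 and 6 h were alike and stood apart from 12 h. Shared DMSO arrays as the whole cause were argued against by 1383 probe sets that differed between 12 h and 3 h without use of DMSO as reference, against 5 between 6 h and 3 h. The covariance of 0.127, where simulations without an effect gave 0.0271, argues only against independent noise of the DMSO arrays. A deviation common to both was not simulated. A batch of hybridization cannot be told apart from exposure time, since the labels give no batch and the hybridization controls of the 3 and 6 h arrays differed from those of DMSO and 12 h by -0.18 ± 0.18. Both 12 h arrays (11.06 and 10.73) lay above every 3 and 6 h array (10.28 to 10.54), and the DMSO arrays (10.34 and 10.36) lay among the latter, so a difference in hybridization goes with 12 h and stays open. Culture time and JH III exposure also remain open, as no time-matched DMSO array separates them.

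The rise of cytosolic ribosomal protein genes at 12 h was weighed last. Quantile normalization brought the median from 0.22 to 0.0072, but 26 of the 29 members were among the 120 brightest probe sets, whose values that method fixes by rank, so the test decides nothing, and median centring gave 0.090 (adjusted p = 3.8e-06). Of 10000 brightness-matched lists the central 95% of medians ended at 0.13 and the highest was 0.23, with 2 as high as the list. The other 94 of the brightest had a median of 0.18 and 81 lay above DMSO, but 61 of these 94 had no single gene symbol (56 above DMSO) and 55 of the 86 genes of the list had no probe set of their own, so ribosomal protein genes may be among them. A shift of bright probe sets at 12 h cannot be told apart from a rise of these genes, and a JH III effect remains untested.

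Differences between exposure times were picked out because the test of the difference passed, without use of DMSO as reference. They numbered 5 between 6 h and 3 h, 1200 between 12 h and 6 h, and 1383 between 12 h and 3 h. From 3 h to 6 h E(spl)mbeta-HLH rose by 1.77 and GstE1 by 0.56, and translation factors had a list median of 0.091 (camera adjusted p = 0.0219; 0.13 without 3 h replicate 1, 0.156 without 6 h replicate 1; adjusted p = 0.466 with an estimated correlation). GstE1 lost its call without any single array of DMSO, 3 h or 6 h (up to 0.208).

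From 6 h to 12 h the called list medians were 0.34 for mitochondrial ribosomal proteins, 0.20 for oxidative phosphorylation, 0.32 for cytosolic ribosomal proteins (0.01 with quantile normalization, adjusted p = 0.513), -0.45 for hemocyte markers, -0.21 for mitosis, -0.33 for germline markers and -0.25 for endoplasmic reticulum stress. With an estimated correlation 0 of these passed in limma's camera, where the lowest adjusted p between times was 0.451. The mitosis call was lost with quantile normalization (camera adjusted p = 0.0573). Those of germline and endoplasmic reticulum stress were lost with median centring (0.0608 each), and germline with the replicate block (0.0519). Mitosis, germline and endoplasmic reticulum stress were also lost at the 60th percentile and without the variance trend (0.0533 to 0.107). Leaving out 6 h replicate 1 also removed the list members unreadable on 6 h replicate 2. Readable on all arrays were 10 of 31 mitosis genes and 11 of 19 hemocyte markers, so smaller lists and the lost array cannot be told apart there. Without 6 h replicate 1 the hemocyte call was lost (adjusted p = 0.0667), as were those of mitosis (0.299), germline (0.274) and endoplasmic reticulum stress (0.0697). Mitosis was also lost without 12 h replicate 1 (0.098). Germline was also lost without 3 h replicate 1 (0.0565), 3 h replicate 2 (0.0593), 12 h replicate 1 (0.13) or 12 h replicate 2 (0.0507). Endoplasmic reticulum stress was also lost without 6 h replicate 2 (0.0755), 12 h replicate 1 (0.0864) or 12 h replicate 2 (0.0535).

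From 3 h to 12 h the called list medians were 0.30 for mitochondrial ribosomal proteins, 0.19 for oxidative phosphorylation, 0.29 for cytosolic ribosomal proteins (0.00 with quantile normalization, adjusted p = 0.619), 0.13 for heat shock proteins, -0.47 for hemocyte markers, -0.39 for germline markers, -0.39 for the insulin and TOR pathway, -0.29 for immediate early and stress kinase genes, -0.14 for mitosis and -0.17 for endoplasmic reticulum stress. With an estimated correlation 0 of these passed either in limma's camera (lowest adjusted p = 0.451). The insulin and TOR call was lost with quantile normalization (camera adjusted p = 0.0573) and at the 60th percentile (0.0533). Mitosis was lost with quantile normalization (0.0925) and median centring (0.0669), and immediate early genes on probe sets readable on all arrays (0.0942). Heat shock was lost with quantile normalization (0.234) and median centring (0.0607), and germline with no filter (0.0875). Heat shock and mitosis were also lost at the 60th percentile (0.089 each) and without the variance trend (0.0914 and 0.107). Endoplasmic reticulum stress was lost with median centring (0.0608), at the 60th percentile (0.102) and without the variance trend (0.107). The heat shock call was lost without any single array except 6 h replicate 2 (adjusted p = 0.0552 to 0.0907). Without 12 h replicate 1 the calls of insulin and TOR (0.0835), germline (0.0821), mitosis (0.123) and endoplasmic reticulum stress (0.0864) were lost. Mitosis was also lost without DMSO replicate 1 (0.0552), DMSO replicate 2 (0.0556), 3 h replicate 2 (0.0973) or 6 h replicate 1 (0.0628). Endoplasmic reticulum stress was also lost without 3 h replicate 1 (0.0687), 3 h replicate 2 (0.0804) or 12 h replicate 2 (0.0507).

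Single genes that rose from 6 h to 12 h were AgmNAT by 2.84, ND-B12 by 1.82, PCB by 1.75, CG3603 by 1.73, ND-B14.5A by 1.65 and ND-B14.5B by 1.57. Those that fell gave -1.80 for Cda4, -1.77 and -1.69 for 2 probe sets of CG32687, -1.75 for Gnpat, -1.59 for Phae1 and -1.53 for CG42554. Cda4 lost its call without 6 h replicate 1 or 12 h replicate 1 (adjusted p up to 0.0997), and Phae1 without 6 h replicate 1 (0.0504). The second CG32687 probe set lost it without either DMSO array, either 6 h array or 12 h replicate 2 (up to 0.175), and CG42554 without any array of DMSO, 6 h or 12 h (up to 0.198).

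Single genes that rose from 3 h to 12 h were AgmNAT by 2.81, CG17806 by 2.01, 1 probe set of l(2)k10201 by 1.95 (the other gave -0.12), ND-B12 by 1.82, CG11368 by 1.78 and ND-B14.5B by 1.73. Those that fell gave -1.81 for Ccp84Ad, -1.75 for Gnpat, -1.75 for wts, -1.70 for CG13877, -1.68 for Vps13B and -1.68 for 1 probe set of Nt5b (the others gave -0.43 and -0.49). Calls were lost without any 3 h or 12 h array for l(2)k10201 (adjusted p up to 0.112) and Ccp84Ad (up to 0.0995), and without 3 h replicate 1 or either 12 h array for CG11368 (up to 0.174). Without 3 h replicate 1 they were lost for Gnpat (0.0673) and Vps13B (0.0746), and without either 3 h array or 12 h replicate 2 for Nt5b (up to 0.0845). For wts the call was lost without any array of DMSO, 3 h or 12 h (up to 0.186), and for CG13877 without either DMSO array, either 3 h array or 12 h replicate 2 (up to 0.172).

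Of the JH list, JhI-26 gave -0.66 from 6 h (1 readable array) to 12 h and -0.39 from 3 h to 12 h, Pepck1 0.36 and Fkbp39 -0.25 from 3 h to 12 h, and Rack1 0.36 from 6 h and 0.30 from 3 h to 12 h. Among array controls, which no comparison used, some lay above both DMSO arrays by more than 2 standard errors. The hybridization controls did so by 0.14 ± 0.05 at 3 h and 0.54 ± 0.16 at 12 h, the actin control by 0.13 ± 0.02 at 3 h and 0.065 ± 0.03 at 6 h, and the eIF4A control by 0.26 ± 0.04 at 12 h. The ratio of 3' to 5' signal, a measure of RNA integrity, did so by 0.29 ± 0.13 for eIF4A at 3 h and by 0.060 for Gapdh at 6 h. The actin ratio lay 0.19, 0.19 and 0.21 above DMSO at 3, 6 and 12 h, by less than 2 standard errors (0.13, 0.10 and 0.12), with all JH III arrays above both DMSO arrays. Below both DMSO arrays by more than 2 standard errors lay the Gapdh control at 3 h (-0.16 ± 0.01) and 12 h (-0.61 ± 0.01), the eIF4A control at 3 h (-0.11 ± 0.04) and the actin control at 12 h (-0.13 ± 0.06).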

How the results depend on the processing

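The use of probe sets readable on all 8 arrays alone, zeros kept as values, counts by gene and fold thresholds were chosen after the data were seen. The other alternatives in this part were planned, and the promoter search for DR4 was not run. Of 248 calls of named probe sets, 225 kept their call and direction with quantile normalization, 222 with median centring, 156 without the variance trend, 145 and 136 without DMSO replicates 1 and 2, and 171 to 219 without 1 JH III array. Of 46 list calls 34, 39, 35, 43 and 36 did under the same settings in turn, 36 to 45 without 1 JH III array, and 46 under both other added constants. Of 19 alternatives, the call was lost in 8 at 3 h and 7 at 12 h for translation factors, in 5, 7 and 8 at 3, 6 and 12 h for ecdysone-responsive genes, in 6 at 3 h for heat shock proteins, and in 0 against DMSO for mitochondrial ribosomal proteins, oxidative phosphorylation and ribosome biogenesis, an estimated correlation not counted. Of the 1572, 1133 and 496 probe sets called at 3, 6 and 12 h, 1274, 904 and 382 were called with quantile normalization and 1191, 869 and 396 with median centring. Detection was limited: 5586 dim probe sets were not tested, and changes of 1.5-fold were found in 43.4% of simulated cases at 3 h. A setting that leaves 1 array in a group assumes that it varies like the other groups.

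With single arrays left out the count ranged from 581 to 1777 at 3 h, 354 to 1313 at 6 h, 82 to 502 at 12 h, 165 to 1272 for the mean, 1048 to 1907 for any difference, 1 to 6 between 6 h and 3 h, 458 to 996 between 12 h and 6 h, 561 to 1380 between 12 h and 3 h, and 20 to 29 for lists. The lowest values came without DMSO replicate 2 (581, 354, 165 and 20), DMSO replicate 1 (82), 6 h replicate 1 (1048 and 458) and 3 h replicate 1 (561), where fewer arrays were used. Without 6 h replicate 1, comparisons that use 6 h also left out the 2611 probe sets unreadable on 6 h replicate 2, and 228 of the 248 named calls could be compared. Correlations ranged from 0.638 to 0.791 for 3 and 6 h, 0.348 to 0.533 for 3 and 12 h, and 0.321 to 0.513 for 6 and 12 h.

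Without the variance trend the counts were 875, 472, 37 and 425 at 3, 6 and 12 h and for the mean, 811 for any difference, and 2, 517 and 685 for 6 h minus 3 h, 12 h minus 6 h and 12 h minus 3 h. Quantile normalization gave 15 for 6 h minus 3 h, and correlations of 0.397 for 3 and 12 h and 0.361 for 6 and 12 h. Median centring gave 889 at 12 h and 2 for 6 h minus 3 h. Without an added constant these correlations were 0.425 and 0.4002, and with 20% of the trimmed mean 0.401 and 0.346. With no filter 2 differed between 6 h and 3 h and correlations were 0.643 for 3 and 6 h and 0.391 for 6 and 12 h. At the 60th percentile these were 15, 0.816 and 0.337. The replicate block gave 305 at 12 h and 2 for 6 h minus 3 h. From only the groups compared, with fewer arrays, the counts were 301 at 12 h, 0 for 6 h minus 3 h by limma (1038 at an unadjusted p under 0.05) and 670 for 12 h minus 6 h. Lists called with an estimated correlation numbered 0 in limma's camera, with 12 at an unadjusted p under 0.05 and 41 by fry. Where no cause is named, the cause was not tested.

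On probe sets readable on all arrays, fewer by construction, the counts were 942, 284, 741 and 1242 at 3 h, at 12 h, for the mean and for any difference, 2 for 6 h minus 3 h and 864 for 12 h minus 3 h, with 18 lists and a correlation of 0.395 for 3 and 12 h. With zeros kept as values, which inflate the spread, 15 and 6 were called at 3 and 6 h, 0 at 12 h (856 at an unadjusted p under 0.05 by limma), 0 for the mean (1237), 50 for any difference, 0 for 6 h minus 3 h (500), 106 for 12 h minus 6 h, 105 for 12 h minus 3 h and 11 lists, with correlations of 0.269 for 3 and 6 h and 0.204 for 6 and 12 h. These zeros turned the 6 h change of 14 named probe sets: Acsl -1.86, kay -1.87, srp -2.30, ImpL2 -2.37, Aldh-III -2.47, Fpps -2.53, eIF4G1 -2.23, tacc -1.69, Cyp4e2 -2.35, CycE -1.84, scyl -1.09, glu -2.60, JhI-21 -2.59 and JhI-26 -1.84, none past the threshold by limma. They also turned the mitosis list from 6 h to 12 h, to 1.87. RpS12 at 12 h turned to -0.18 with quantile normalization (adjusted p = 0.0208), and that cause was not tested.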

Other observations

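No test in this part was chosen after the results were seen, except that the dim probe sets were examined afterwards. Cell cycle genes and regulators moved singly at 3 h, where their lists were not called. E2f1, a transcription factor of S phase entry, rose 2.09-fold at 3 h (1.07 ± 0.13, adjusted p = 0.0011), CycE rose by 0.83 ± 0.13, and tacc, a centrosome gene, rose by 1.01 ± 0.11 at 3 h and by 0.85 ± 0.14 at 6 h (1 readable array). For Stat92E, the JAK-STAT transcription factor, 1 probe set rose by 0.77 ± 0.11 at 3 h and the other gave 0.12 (adjusted p = 0.64). The amino acid transporter gene path rose by 0.99 ± 0.12 at 6 h (adjusted p = 0.00179), and GstD9 fell by 0.60 ± 0.07 at 6 h. Cyp4e2 rose by 0.61 ± 0.09 at 3 h. Fpps, of the JH synthesis and turnover list, rose by 0.71 ± 0.10 at 6 h (1 readable array). The DNA replication list gave medians of -0.05 and -0.03 at 3 and 6 h (camera adjusted p = 0.65 and 0.886), and mitosis gave 0.02, 0.09 and -0.08 at 3, 6 and 12 h (0.371, 0.181 and 0.305).

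Other lists not called against DMSO had these medians at 3, 6 and 12 h, with camera adjusted p in brackets. JH synthesis and turnover gave 0.04, 0.15 and -0.01 (0.819, 0.464 and 0.677), nuclear receptors 0.24, 0.21 and 0.07 (0.3, 0.303 and 0.853), cytochrome P450 0.11, 0.21 and -0.01 (0.171, 0.181 and 0.498), and glutathione and UDP transferases 0.16, 0.10 and -0.02 (0.303, 0.318 and 0.646). The proteasome gave -0.05, -0.03 and -0.01 (0.348, 0.148 and 0.886), the immune response 0.09, -0.01 and -0.11 (0.582, 0.694 and 0.677), glycolysis -0.11, -0.08 and -0.11 (0.318, 0.305 and 0.171), amino acid transporters 0.08, 0.04 and 0.01 (0.886, 0.822 and 0.628), and apoptosis 0.02, 0.07 and -0.03 (0.633, 0.926 and 0.886). Among the marker lists, muscle gave -0.16, 0.19 and -0.02 (0.918, 0.498 and 0.972), fat body 0.06, 0.28 and 0.15 (0.822, 0.276 and 0.565), and germline 0.33, 0.26 and -0.09 (0.0662, 0.116 and 0.643). Median centring or quantile normalization changed the sign of at least 1 of these medians for every list in this paragraph except glycolysis, muscle and germline. The mitosis medians at 3 and 6 h changed sign with median centring.

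The 5586 dim probe sets left out had a median change of 0.05, 0.12 and 0.09 at 3, 6 and 12 h, and 58.1%, 68.3% and 63.7% of them lay above DMSO, against 53.6%, 55.7% and 50.6% of those tested. The first principal component held 32.6% of the variance and the second 16.2%. On the first, the DMSO arrays (-11.6 and -14.8) lay with the 12 h arrays (-14.8 and -13.5). The 3 h arrays (15.5 and 14.8) and 6 h arrays (13.2 and 11.1) lay on the other side. The second parted DMSO (-12.4 and -14.8) from 12 h (14.9 and 11.8).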
